A study of Caenorhabditis elegans with 24 samples.

How the data were processed

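The study measured polyadenylated RNA in cells isolated from wild-type Caenorhabditis elegans hermaphrodites at 4 stages: the end of larval stage L3, the start and the end of L4, and adulthood. At each stage a Venus-positive fraction, labelled as distal tip cells (DTCs), and a Venus-negative fraction, labelled as other cells, were taken, with 3 samples per group, which gives 8 groups and 24 libraries. Per the labels' protocols, animals grew at 20 °C on OP50 bacteria, 30000 to 60000 cells were used per sample, RNA was extracted with an miRNeasy kit, and libraries were made with Nextera XT from 1 ng of cDNA. Per the submitters' processing notes, reads were inspected with FastQC, trimmed with cutadapt, aligned to the ce11 build with Bowtie2 and counted per gene with HTSeq; tool versions and the strand setting of the counting are not given in the sources used here.

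The deposited counts are 1 table of whole raw read counts with 46778 gene IDs and 24 sample columns, of which every column was used and mapped to its sample by the column's name. Every ID names a gene; 43818 IDs (93.7%) had a symbol in the names table used and 46603 (99.6%) lay in the WBcel235 annotation of Ensembl release 115, which is the same assembly as ce11 and gives the positions printed. Total counts per library ran from 8391423 to 18045720. Genes with near-identical copies share reads in a way the counting could split, so single members of the msp, nsp, vit, act, fbxa and col families are uncertain. The same holds for overlapping genes on opposite strands, since the strand setting is not known; among the genes named, nhr-101 and ssq-4 share most of their exon sequence with genes on the opposite strand, and hlh-12 and hhat-1 lie inside the spans of spp-10 and unc-52 on the opposite strand.

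Computation from the deposited counts was as follows. Genes were kept by filterByExpr over the 8 groups in edgeR 4.0.16 under R 4.3.3, which left 16887 genes. Libraries were scaled by TMM, and 1 quasi-likelihood model with 8 group means was fitted to all 24 libraries. Every comparison shares 1 spread estimate (common biological coefficient of variation 0.835). Root mean square log2 deviations from group means were 0.645 to 0.675 in other cells at early L4 and 1.203 to 1.34 in adults. P-values may thus be too small in adults and too large at early L4. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and "adjusted p" below means that value unless a gene list is named. The error printed after a log2 fold change is its standard error, computed from the fold change and the quasi-likelihood F statistic. Scaling is relative to all RNA in a library, so a change is a change in share. The labels do not say whether the 3 samples of a group come from separate cultures, so p-values measure only the spread between these samples.

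The comparisons were DTCs against other cells at each stage and as the mean of the 4 stages, any difference among the 4 stages within DTCs, the 3 steps between successive stages in DTCs and in other cells, and the difference between the DTC step and the step in other cells, tested per step and over all steps. Where a group had 0 counts of a gene, the ratio is a lower bound against 3 counts over the group; where it had 1 to 3 counts the ratio of CPM values (reads scaled to the library size) is given with a 95% counting interval. For the mean of the 4 stages and the differences between fractions these were computed per group from summed counts and combined as mean or ratio of ratios. Those bounds and intervals cover counting error only. Fitted fold changes of such genes depend on the prior count and are no bound. Principal components were taken from the 1000 most variable genes on the log2 CPM scale with a prior count of 2.

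The 34 gene lists tested were written from general knowledge before the data were examined. Those reported here were germline stem cell niche and known DTC genes, guidance receptors and ligands, the Notch pathway, integrin and cell adhesion, the actin and myosin cytoskeleton, the microtubule cytoskeleton, basement membrane, secreted metalloproteases and inhibitors, endoplasmic reticulum (ER) folding and collagen modification, ER to Golgi trafficking, endocytosis, vacuolar ATPase and lysosome, ribosomal proteins, oxidative phosphorylation, glycolysis and pyruvate entry, the proteasome, heat shock and stress response, developmental timing, gap junction innexins, cell cycle and DNA replication, and collagens of the col class. Markers were listed for germline, oocyte, sperm, intestine, body wall muscle, pharynx, hypodermis and cuticle, neurons, glia, coelomocytes, gonadal sheath and spermatheca, and the excretory system. In all, 17 listed genes matched no symbol in the table and were left out. Each list was tested against all other genes with limma 3.58.1 (camera, inter-gene correlation 0.01), adjusted over the 34 lists of a comparison; camera with an estimated correlation, and fry, which asks whether a list's genes move on balance 1 way or in either direction, were run beside it. Counts of members are given over all genes tested and adjusted over the list alone.

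The genes named in the text follow a rule fixed before the data were examined, as were the comparisons, the lists, the main model and the first set of other settings. For the mean of the 4 stages, the rule names the 10 genes with the highest and the 10 with the lowest fold change among those called, with an average log2 CPM of at least 5 and with DTC and other-cell libraries separated at all 4 stages. In other comparisons it names 8 and 8 under the same abundance minimum, without overlap of the groups where 2 groups are compared. It also names up to 4 members of each list with the smallest p, and a fixed set of genes including lag-2, hlh-12, unc-5, gon-1, emb-9, let-2, mig-6, the integrin genes and the heterochronic genes.

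The other settings fixed at that time were DESeq2 1.42.0, size factors of its kind (RLE) in edgeR, no filter on low counts, voom with sample quality weights, a fit of only the groups compared, the replicate number as a block, and each library left out in turn. Settings chosen after seeing the data were leaving out rRNA genes, averaging only the 3 larval stages, and reading every comparison without other cells late L3 replicate 3. The labels number the samples of each group from 1 to 3. Whether the numbers pair the DTC sample with the other-cell sample of its stage was checked by the correlation of their deviations from the group means. At late L3 same-numbered pairs correlated at 0.16, 0.115 and 0.248. DTC 1 with other cells 2 gave 0.162, so only replicate 3 looked paired. At other stages the lowest pair was 0.028, 0.036 and -0.058, and pairing was unclear. Between stages, same-numbered samples of other cells at late L3 and late L4, which were not compared with each other, correlated at a mean of 0.201 and at least 0.138.

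The model was tested on simulated data with the real genes, means and library sizes and known changes in a seeded set of 200 genes. The spread was drawn from edgeR's own estimates, which may favour edgeR over the other tools. In the mean of the 4 stages it recovered 23.4%, 75% and 77.8% of genes changed 2-fold, 4-fold and 8-fold, and 4.3% of its calls were false. For DTCs against other cells at late L3 it recovered 1.5%, 13.6% and 38.2% with 5.3% false, while DESeq2 recovered 10.6%, 39.4% and 66.2% with 37.1% false and voom had 15.4% false. For the step from late L3 to early L4 it recovered 0%, 15.2% and 43.9% in DTCs and 1.4%, 25% and 32.3% in other cells, and for the difference between fractions in the step from early to late L4 0%, 6.2% and 13.4%. Such changes between single groups were thus mostly missed, but with more genes changed recovery may be higher. A simulated change of 1 list ranked it 1 of 34 in camera with 0 false lists, with co-varying lists untested. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.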

Results

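RNA was counted in 24 libraries of C. elegans hermaphrodite cells. They came from a Venus-positive fraction holding distal tip cells (DTCs) and a Venus-negative fraction of other cells at 4 stages, with 3 libraries per group. The DTC caps each arm of the gonad, leads its migration during larval stages and acts as the niche of the germline stem cells. The series asks, per its title, which transcripts equip such a leader cell at each stage. Total counts per library averaged 15.55, 15.14, 12.21 and 11.65 (in units of 1e+06 reads) in DTCs from late L3 to adult, and 17.09, 17.55, 12.07 and 12.83 in other cells. Ribosomal RNA took 7.25% to 33.21% of counts and mitochondrial RNA 0.46% to 4.14%. The library of other cells labelled late L3 replicate 3 scored 19.157 on the first principal component, while replicates 1 and 2 of its group scored -114.357 and -107.507. It also held 0.371% of counts in sperm genes against 0.00228% and 0.00335%, and 0.231% in hypodermis genes against 2.46% and 2.65%.

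**Figure D1:**
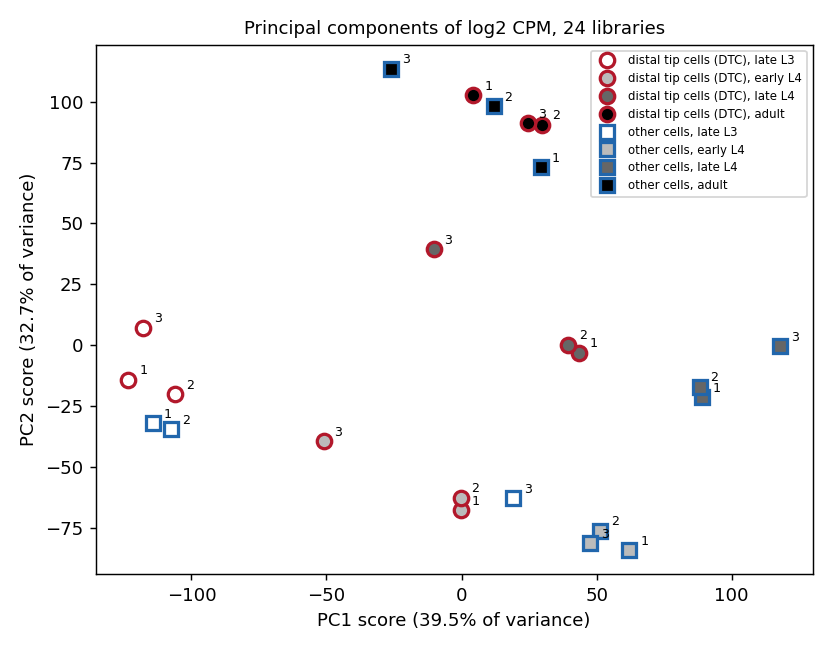
Scores of the 24 libraries on the first (39.5% of variance) and second (32.7%) principal component of log2 CPM; circles are DTCs, squares are other cells, darker fill marks later stages and digits are replicate numbers. The square of late L3 replicate 3 lies at 19.157 on the first axis, apart from -114.357 and -107.507 for the other late L3 squares.

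The mean over the 4 stages asked which transcripts mark DTCs whatever the stage, and the niche gene lag-2 was among the highest. Numbers in brackets after a gene are log2 fold changes ± standard error from edgeR, here with 12 libraries of DTCs against 12 of other cells. Genes so given were called unless the sentence says otherwise, and a bound or ratio replaces the value where a group held 3 counts or fewer. By fitted value, whose order is not exact for genes given by a bound or ratio, the highest genes whose DTC and other-cell libraries were separate at all 4 stages were fbxa-154 (at least 678-fold higher), srt-62 (at least 357-fold higher), lag-2 (a ratio of 287, 187 to 720), mig-21 (7.93 ± 0.65) and cyn-17 (at least 54.7-fold higher). They were followed by nid-1 (6.54 ± 0.35), catp-5 (6.43 ± 0.72), igcm-2 (at least 26.1-fold higher), lron-2 (at least 23.9-fold higher) and fbxb-88 (5.54 ± 0.56). Of these, fbxa-154 and fbxb-88 encode F-box proteins, srt-62 a putative chemoreceptor, lag-2 the Notch ligand that DTCs present to the germline, and nid-1 nidogen, a basement membrane linker. In DTCs lag-2 stood at 209 ± 26.3 CPM at late L3, 194 ± 10.8 at early L4, 245 ± 46.4 at late L4 and 34 ± 6.01 in adults (mean ± SD, n = 3). No group of other cells averaged above 1.84 CPM of lag-2. The adjusted p was 1.12e-09 for fbxa-154 and 1.45e-09 for lag-2. Their positions on ce11 are V 15602882 to 15605145 for fbxa-154 and V 3188343 to 3190115 for lag-2.

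Matrix genes were higher in the mean, with type IV collagens emb-9 (3.64 ± 0.19) and let-2 (3.56 ± 0.22), laminin epi-1 (3.87 ± 0.20), papilin mig-6 (3.20 ± 0.18), and the collagen-modifying enzymes let-268 (3.66 ± 0.20) and phy-2 (2.74 ± 0.26). The secreted protease gon-1 (3.69 ± 0.69), which gonad migration needs, and the migration factor hlh-12 (5.17 ± 0.46) were higher. So were the netrin receptors unc-5 (2.89 ± 0.40) and unc-40 (1.40 ± 0.18), the Frizzled gene lin-17 (2.86 ± 0.29), the integrins ina-1 (2.96 ± 0.17) and pat-3 (1.24 ± 0.17), dystroglycan dgn-1 (3.59 ± 0.15), syndecan sdn-1 (2.53 ± 0.13) and semaphorin smp-1 (2.15 ± 0.18). The gap junction gene inx-9 (4.45 ± 0.16), FoxA gene pha-4 (4.11 ± 0.17), SoxD gene egl-13 (3.39 ± 0.28) and microtubule organiser ptrn-1 (3.8 ± 0.20) were higher. Also higher were non-muscle myosin nmy-1 (1.07 ± 0.16), the second Notch ligand apx-1 (2.52 ± 0.27) and the nuclear receptor daf-12 (2.51 ± 0.25). The lowest genes separate at all 4 stages were the ligand-gated channel gene lgc-26 (-3.73 ± 0.43), coelomocyte gene unc-122 (-3.38 ± 0.35), nspc-9 (-2.99 ± 0.38) and sams-5 (-2.85 ± 0.46). They were followed by ddo-3 (-1.94 ± 0.35), aass-1 (-1.28 ± 0.25), separase sep-1 (-1.08 ± 0.19) and the replication gene mcm-5 (-0.94 ± 0.22). Troponin tni-3 (-2.06 ± 0.28), muscle myosin myo-3 (-1.46 ± 0.35), the Notch receptor lin-12 (-2.32 ± 0.33) and hbl-1 (-2.28 ± 0.80) were lower. The call of hbl-1 was lost when any of 8 libraries was left out.

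In total 5163 of 16887 genes were called, 2753 higher and 2410 lower in DTCs, and every fit with a library left out called 4303 to 5693. RLE scaling gave 2254 higher and 3369 lower and moved the median of all genes from -0.14 to -0.33, so directions of small changes depend on scaling. Gene lists are given below with the count over all genes, then the count adjusted over the list alone. The niche and known DTC genes had 11 of 15 higher (11 alone, median 2.89, adjusted p = 2.21e-14). Basement membrane genes had 13 of 25 higher and 2 lower (13 and 3 alone, median 1.35, adjusted p = 2.14e-20). Guidance genes had 18 of 34 higher and 5 lower (18 and 6 alone, median 0.90, adjusted p = 9.22e-06). Integrin and adhesion genes had 15 of 26 higher and 2 lower (16 and 3 alone, median 0.65, adjusted p = 1.6e-05). ER folding genes had 15 of 27 higher (17 alone, median 0.44, adjusted p = 2.24e-08) and ER to Golgi genes 20 of 32 higher (20 alone, median 0.49, adjusted p = 3.64e-06). Timing genes had 10 of 24 higher and 4 lower (12 and 4 alone, median 0.63, adjusted p = 0.00321) and innexins 7 of 24 higher and 1 lower (8 and 2 alone, median 0.20, adjusted p = 0.013). These 8 lists also passed with an estimated correlation.

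Further lists passed only at the preset correlation. Actin and myosin genes had 23 of 48 higher and 10 lower (23 and 10 alone, median 0.37, adjusted p = 0.00284, adjusted p = 0.0691 with an estimated correlation). Microtubule genes had 13 of 33 higher and 4 lower (14 and 4 alone, median 0.19, adjusted p = 0.00436, adjusted p = 0.114 with an estimated correlation). Secreted metalloproteases had 9 of 22 higher and 2 lower (9 and 2 alone, median 0.23, adjusted p = 0.0063, adjusted p = 0.114 with an estimated correlation). Endocytosis genes had 16 of 27 higher and 1 lower (16 and 1 alone, median 0.59, adjusted p = 0.00057, adjusted p = 0.0894 with an estimated correlation). Muscle markers had 18 of 23 lower and 1 higher (19 and 1 alone, median -1.46, adjusted p = 1.27e-09, adjusted p = 0.136 with an estimated correlation). Sperm markers had 46 of 56 lower (49 and 1 alone, median -2.88, adjusted p = 9.28e-09, adjusted p = 0.417 with an estimated correlation). Without other cells late L3 replicate 3 they had 14 lower and 2 higher (median -1.21). Col collagens had 65 of 137 lower (75 alone, median -1.46, adjusted p = 4.19e-10, adjusted p = 0.146 with an estimated correlation). Cell cycle genes had 16 of 32 lower (20 alone, median -0.68, adjusted p = 7.79e-06, adjusted p = 0.218 with an estimated correlation), with 25 lower under RLE.

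Germline markers had 13 of 29 lower (15 alone, median -0.51, adjusted p = 6.39e-05, adjusted p = 0.287 with an estimated correlation) in the mean over stages, with 21 lower under RLE. Oocyte markers had 12 of 19 lower (14 alone, median -0.80, adjusted p = 0.000231, adjusted p = 0.304 with an estimated correlation). Glia markers had 5 of 9 lower (6 alone, median -1.61, adjusted p = 0.00231, adjusted p = 0.0894 with an estimated correlation). Coelomocyte markers had 4 of 6 lower and 1 higher (4 and 1 alone, median -3.11, adjusted p = 0.000604, adjusted p = 0.0894 with an estimated correlation). Hypodermis markers had 7 of 32 lower (1 alone, median -1.36, adjusted p = 0.00362, adjusted p = 0.41 with an estimated correlation). Ribosomal protein genes had 0 of 80 lower (0 alone, median -0.18, adjusted p = 0.0128, adjusted p = 0.724 with an estimated correlation), with 35 lower under RLE. Oxidative phosphorylation genes had 4 of 45 lower (0 alone, median -0.19, adjusted p = 0.0304, adjusted p = 0.612 with an estimated correlation), with 25 lower under RLE and 0 without other cells late L3 replicate 3.

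The remaining lists did not pass as groups. Notch pathway genes had 7 of 23 higher and 2 lower (7 and 2 alone, median -0.03, adjusted p = 0.187), with a mean of 0.31 and an upward test. Heat shock genes had 7 of 23 higher and 2 lower (8 and 2 alone, median 0.21, adjusted p = 0.284). Proteasome genes had 6 of 31 higher (5 alone, median 0.12, adjusted p = 0.25), and 1 higher and 4 lower under RLE (median -0.06). Vacuolar ATPase and lysosome genes had 5 of 35 higher and 5 lower (7 and 6 alone, median 0.12, adjusted p = 0.775), with a mean of -0.04, and under RLE 10 lower and a median of -0.08. Glycolysis genes had 6 of 23 lower and 3 higher (7 and 4 alone, median -0.05, adjusted p = 0.362), with 10 lower under RLE. Neuron markers had 13 of 58 lower and 8 higher (13 and 8 alone, median -0.77, adjusted p = 0.246), with the neuropeptide gene flp-10 (3.62 ± 0.22) among the higher. Pharynx markers had 5 of 16 lower and 1 higher (7 and 1 alone, median -0.82, adjusted p = 0.187). Excretory markers had 3 of 10 lower and 1 higher (3 and 1 alone, median -0.71, adjusted p = 0.302). Sheath and spermatheca markers had 3 of 11 higher (3 and 1 alone, median -0.16, adjusted p = 0.551) and intestine markers 2 of 21 lower and 1 higher (2 and 1 alone, median 0.00, adjusted p = 0.665), and in both the median, mean and test differed in sign.

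**Figure D2:**
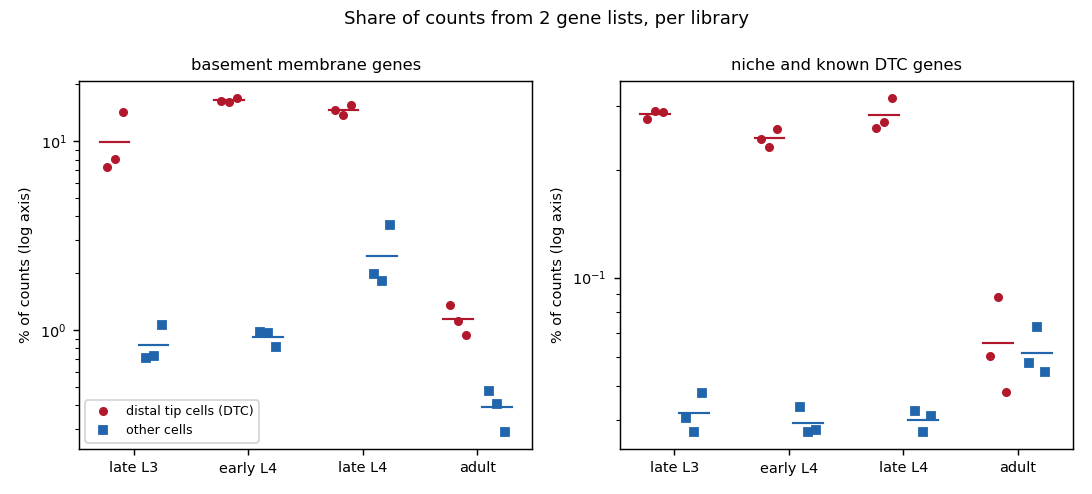
Share of a library's counts (%, log axis) from basement membrane genes and from niche and known DTC genes, by stage; points are single libraries, lines are means of 3, circles are DTCs and squares other cells. Basement membrane genes averaged 14.6% of counts in late L4 DTCs and 1.14% in adult DTCs, against 2.46% and 0.389% in other cells.

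At late L3, when the gonad arms are migrating, niche and basement membrane genes were above other cells. With 3 libraries on each side, fbxa-154 had 11449 counts in DTCs and 0 in other cells, which makes it at least 4190-fold higher. The bHLH gene hlh-12 (10.45 ± 1.13), at IV 8478595 to 8479446, stood at 375 ± 4.85 CPM in DTCs (SD, n = 3) against 0.289 in other cells. The peroxidase gene skpo-1 (8.91 ± 0.72), srt-62 (8 ± 1.40), nid-1 (7.73 ± 0.73), lag-2 (7.48 ± 1.08), mig-21 (7.03 ± 1.26) and inx-9 (5.17 ± 0.34) followed. Matrix genes emb-9 (4.05 ± 0.39), mig-6 (4.02 ± 0.37), let-268 (3.93 ± 0.40) and let-2 (3.82 ± 0.44) were higher, as were the receptors dgn-1 (4.13 ± 0.30), unc-5 (3.55 ± 0.82) and ina-1 (3.34 ± 0.34). Also higher were flp-10 (4.56 ± 0.45), apx-1 (2.63 ± 0.54), daf-12 (2.56 ± 0.50) and pha-4 (2.52 ± 0.32), while the fold change of gon-1 (4.04 ± 1.37, adjusted p = 0.0563) missed the threshold. The yolk protein gene vit-2 had 84 counts against 0 (at least 30.8-fold), and vit-6 113 against 1, a ratio of 124 (21.8 to 4950). Lower were the muscle genes myo-3 (-3.62 ± 0.75), mup-2 (-3.47 ± 0.56), lev-11 (-3.01 ± 0.37), cpn-3 (-3.82 ± 0.59) and zyx-1 (-2.75 ± 0.29), and the integrin pat-2 (-2.83 ± 0.64). The coelomocyte genes cup-4 (-5.67 ± 0.75) and unc-122 (-5.21 ± 0.77), and the glial gene vap-1 (-4.69 ± 0.68), were lower too.

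The lowest genes at late L3 included sperm genes. In DTCs acs-10 had 0 counts against 3155 (at least 957-fold lower) and spch-2 0 against 1272 (at least 386-fold lower). For acdh-8 there was 1 count against 2181, a ratio of 1980 (356 to 78400). Next came msp-31 (-8.60 ± 1.77), nsph-3.1 (-8 ± 1.68), ssq-4 (-7.08 ± 1.61), clec-73 (-6.54 ± 1.90) and msp-49 (-6.48 ± 1.41). Other cells late L3 replicate 3 held 3067, 1237 and 2037 of the counts of acs-10, spch-2 and acdh-8. Without it they were at least 40.1-fold and 16-fold lower and lower by a ratio of 197 (34.8 to 7830), still called, while the calls of these last 5 genes were lost. A fit of only the groups compared, which called 1061 genes, ended all these calls but that of acdh-8, and those of vit-2 and vit-6. Without that library sperm markers moved from 37 of 56 lower (45 alone, median -6.23, adjusted p = 4.33e-05, adjusted p = 0.558 with an estimated correlation) to 2 higher and 2 lower (median 0.00). The comparison called 2256 genes, 1019 higher and 1237 lower, or 676 and 1609 under RLE. Without DTC replicate 1 it called 1494 and without DTC replicate 3 it called 1224.

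Among lists at late L3, niche genes had 9 of 15 higher (12 alone, median 3.23, adjusted p = 2.55e-12). Basement membrane genes had 13 of 25 higher and 4 lower (13 and 8 alone, median 2.18, adjusted p = 6.39e-10), and both lists passed with either correlation. Muscle markers had 18 of 23 lower (18 and 1 alone, median -3.07, adjusted p = 1.31e-16, adjusted p = 0.0999 with an estimated correlation). ER folding genes had 8 of 27 higher (11 and 1 alone, median 0.67, adjusted p = 5.65e-06, adjusted p = 0.0999 with an estimated correlation). Oxidative phosphorylation genes had 6 of 45 lower (20 alone, median -0.59, adjusted p = 5.98e-05, adjusted p = 0.36 with an estimated correlation), with 27 lower under RLE and 2 lower and 1 higher without other cells late L3 replicate 3. Guidance genes had 6 of 34 higher and 4 lower (9 and 7 alone, median -0.40, adjusted p = 0.703) and integrin genes 9 of 26 higher and 6 lower (10 and 7 alone, median 0.64, adjusted p = 0.216), and neither passed. Coelomocyte markers had 3 of 6 lower (3 and 1 alone, median -2.27, adjusted p = 0.0173, adjusted p = 0.303 with an estimated correlation). The coelomocyte list did not pass with the replicate number as a block (adjusted p = 0.0798), and the block also ended the calls of vit-6 and nsph-3.1. The call of vit-6 was lost when any of 5 libraries was left out.

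At early L4 genes of adhesion, cytoskeleton and secretion were higher in DTCs along with niche and matrix genes. The highest were fbxa-154 (10.85 ± 0.91), catp-5 (9.78 ± 1.66), srt-62 (9.69 ± 1.48), the potassium channel gene egl-36 (8.53 ± 1.04) and hlh-12 (8.34 ± 1.04). They were followed by fbxb-88 (8.31 ± 1.27), mig-21 (7.78 ± 1.29), lron-2 (7.46 ± 0.84) and lag-2 (7.33 ± 1.07). Matrix genes emb-9 (5.01 ± 0.41), let-2 (4.93 ± 0.46) and mig-6 (4.90 ± 0.39) were higher, with their receptors dgn-1 (4.96 ± 0.31), ina-1 (4.09 ± 0.36), sdn-1 (3.52 ± 0.26) and pat-3 (2.21 ± 0.34). The netrin receptors unc-5 (2.96 ± 0.80) and unc-40 (2.07 ± 0.37), the microtubule gene ptrn-1 (5.71 ± 0.45) and the adhesion gene unc-97 (3.40 ± 0.37) were higher. Secretion genes let-268 (4.25 ± 0.41), dnj-7 (4.06 ± 0.36), sec-22 (3.38 ± 0.46) and pdi-6 (3.16 ± 0.36) were higher, as were apx-1 (3.35 ± 0.56), daf-12 (3.20 ± 0.52) and nmy-1 (1.35 ± 0.32). Lower were vap-1 (-4.17 ± 0.66), ule-4 (-3.62 ± 1.05), col-119 (-3.40 ± 0.91), grd-5 (-3.22 ± 0.53), grd-3 (-3.21 ± 0.66), nspc-4 (-3.01 ± 0.66) and tni-3 (-2.32 ± 0.56). In DTCs spex-3 had 0 counts against 32 (at least 9.2-fold lower) and nhr-25 1 against 159, a ratio of 137 (24.3 to 5450). In all 1866 genes were called, 1587 higher and 279 lower, or 1214 and 437 under RLE, and 1105 (889 and 216) without other cells replicate 3. Leaving out some library ended the calls of unc-5, nhr-25, spex-3, ule-4 and col-119, and leaving out other cells replicate 3 that of nmy-1.

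At early L4 the following lists were higher with either correlation. Niche genes had 10 of 15 higher and 1 lower (12 and 1 alone, median 3.13, adjusted p = 1.24e-10) and basement membrane genes 12 of 25 higher (12 and 3 alone, median 1.19, adjusted p = 1.81e-16). Guidance genes had 13 of 34 higher (17 and 1 alone, median 0.97, adjusted p = 9.22e-06) and integrin genes 13 of 26 higher and 3 lower (14 and 4 alone, median 1.08, adjusted p = 1.8e-06). Actin genes had 17 of 48 higher and 1 lower (23 and 4 alone, median 0.70, adjusted p = 1.29e-05). Microtubule genes had 11 of 33 higher (14 alone, median 0.62, adjusted p = 4.32e-06), 7 under RLE, and endocytosis genes 11 of 27 higher (15 and 1 alone, median 0.96, adjusted p = 3.69e-07). ER folding genes had 11 of 27 higher (15 alone, median 0.78, adjusted p = 1.86e-08) and ER to Golgi genes 12 of 32 higher (18 alone, median 0.73, adjusted p = 3.55e-07), 7 under RLE. At the preset correlation alone, col collagens had 5 of 137 lower (0 alone, median -1.79, adjusted p = 3.13e-08, adjusted p = 0.27 with an estimated correlation) and muscle markers 6 of 23 lower and 1 higher (14 and 1 alone, median -1.54, adjusted p = 4.69e-05, adjusted p = 0.456 with an estimated correlation).

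At late L4 niche and guidance genes stayed above other cells, while hlh-12 (1.25 ± 0.79, adjusted p = 0.322) was not called. DTCs held 4085 counts of srt-62 against 0 (at least 1350-fold) and 2530 of fbxa-154 against 0 (at least 834-fold). Next came mig-21 (10.20 ± 1.44), lag-2 (8.48 ± 1.14), pll-1 (6.89 ± 0.93), fbxb-88 (6.83 ± 1.17), cyn-17 (6.74 ± 1.22) and nid-1 (6.53 ± 0.69). Guidance genes smp-1 (4.43 ± 0.39), unc-5 (3.67 ± 0.83), unc-40 (2.71 ± 0.38) and the ephrin receptor vab-1 (2.85 ± 0.30) were higher. Matrix receptors dgn-1 (4.43 ± 0.31), sdn-1 (3.64 ± 0.27), ina-1 (3.49 ± 0.35), pat-3 (1.67 ± 0.34) and pat-2 (1.99 ± 0.62) were higher, the last of these lost under RLE and when a library was left out. The matrix genes emb-9 (3.28 ± 0.38), let-2 (3.16 ± 0.43), mig-6 (2.33 ± 0.34) and metalloprotease zmp-1 (3.52 ± 0.36) were higher. So were inx-9 (5.16 ± 0.34), the Argonaute alg-1 (2.72 ± 0.31), din-1 (2.70 ± 0.38), daf-12 (3.02 ± 0.51) and apx-1 (2.42 ± 0.54). Genes lgc-26 (-5.15 ± 0.92), cup-4 (-4.75 ± 0.72) and unc-122 (-4.43 ± 0.74) were lower, with lgc-28 (-5.02 ± 0.92), clec-145 (-4.98 ± 1.14), ttr-1 (-4.69 ± 0.73), aman-1 (-4.65 ± 0.79) and cubn-1 (-4.56 ± 1.1). Also lower were cht-3 (-4.47 ± 1.35), tni-3 (-3.15 ± 0.58), perm-4 (-2.75 ± 0.79) and eggshell gene cpg-1 (-1.85 ± 0.40), with cht-3 and perm-4 lost when some library was left out. In all 1992 genes were called, 1552 higher and 440 lower, or 1254 and 625 under RLE. Without DTC replicate 3, which held 0.281% of counts in muscle genes against 1.55% and 1.33%, 1157 were called.

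Lists higher at late L4 with either correlation were as follows. Niche genes had 8 of 15 higher (10 alone, median 2.71, adjusted p = 2.91e-10) and basement membrane genes 12 of 25 higher and 2 lower (12 and 4 alone, median 1.55, adjusted p = 1.07e-08). Guidance genes had 13 of 34 higher and 1 lower (14 and 3 alone, median 1.34, adjusted p = 1.48e-06) and integrin genes 10 of 26 higher (14 and 2 alone, median 1.14, adjusted p = 1.38e-05). Timing genes had 8 of 24 higher (9 and 2 alone, median 1.19, adjusted p = 0.000746). Muscle markers had 12 of 23 lower (18 alone, median -1.79, adjusted p = 1.26e-09, adjusted p = 0.244 with an estimated correlation) and oocyte markers 7 of 19 lower (10 alone, median -1.29, adjusted p = 1.48e-06, adjusted p = 0.281 with an estimated correlation).

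In adults the niche ligand and matrix genes were above other cells, while several migration receptors were not called. Adult DTCs held 1142 counts of lag-2 against 1, a ratio of 1260 (225 to 49700). They held 374 of cyn-17 (at least 137-fold), 248 of srt-62 (at least 91-fold) and 190 of lron-2 (at least 69.7-fold), each against 0, and fbxa-154 was at least 47.3-fold higher. The formin daam-1 (at least 23.8-fold higher), igcm-2 (at least 25.3-fold higher) and gon-1 (5.64 ± 1.58) were higher. Matrix genes nid-1 (4.57 ± 0.63), epi-1 (3.40 ± 0.38), let-268 (2.93 ± 0.39), lam-2 (2.80 ± 0.49), let-2 (2.35 ± 0.41), emb-9 (2.2 ± 0.36) and mig-6 (1.53 ± 0.34) were higher, as were inx-9 (2.75 ± 0.30), nmy-1 (2.18 ± 0.33) and apx-1 (1.67 ± 0.53). By contrast hlh-12 (0.64 ± 0.80, adjusted p = 0.649), unc-5 (1.40 ± 0.77, adjusted p = 0.234), ina-1 (0.90 ± 0.32, adjusted p = 0.064), pat-3 (0.12 ± 0.33, adjusted p = 0.87) and unc-40 (-0.26 ± 0.35, adjusted p = 0.693) were not called. Intestinal actin act-5 (1.36 ± 0.26), ifc-2 (2.59 ± 0.60), ferritin ftn-1 (3.20 ± 1.01) and the pharynx myosins myo-1 (2.92 ± 0.59) and myo-2 (2.77 ± 0.70) were higher, while yolk genes vit-2 (2.52 ± 0.90, adjusted p = 0.0725) and vit-6 (2.94 ± 1.23, adjusted p = 0.116) were not called. Germline and chromosome genes htp-3 (-3.71 ± 0.49), rrf-3 (-2.70 ± 0.46), mcm-3 (-1.91 ± 0.29), glh-1 (-1.88 ± 0.30) and bub-1 (-1.82 ± 0.30) were lower. Other lower genes were the neuropeptide genes flp-1 (-3.44 ± 0.89) and nlp-49 (-2.76 ± 0.91), zig-2 (-3.38 ± 0.74), hcf-1 (-2.77 ± 0.37) and metl-17 (-2.62 ± 0.38).

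The adult comparison called 2248 genes, 1383 higher and 865 lower, but 1180 without DTC replicate 1 and 1236 without DTC replicate 3. Leaving out some library ended the calls of gon-1, apx-1, igcm-2, myo-2, ftn-1 and nlp-49, the last also lost under RLE. Those of daam-1 and flp-1 were lost without DTC replicate 3 and that of ifc-2 without other cells replicate 1. A fit of only the groups compared called 395 genes and ended the calls of fbxa-154, daam-1, igcm-2, gon-1, lam-2, mig-6, apx-1, act-5, ifc-2, ftn-1, myo-2 and rrf-3, and voom ended that of cyn-17. Of the 37 genes called and named by the rule, 20 kept their calls under every other setting. Basement membrane genes had 15 of 25 higher (18 alone, median 1.53, adjusted p = 4.09e-12), with either correlation. Germline markers had 18 of 29 lower (26 alone, median -1.49, adjusted p = 1.2e-19, adjusted p = 0.0644 with an estimated correlation). Cell cycle genes had 18 of 32 lower (22 alone, median -1.48, adjusted p = 4.69e-18, adjusted p = 0.0644 with an estimated correlation). Niche genes had 4 of 15 higher (5 alone, median 0.99, adjusted p = 0.0101, adjusted p = 0.0784 with an estimated correlation). Intestine markers had 3 of 21 higher (3 alone, median 1.41, adjusted p = 0.00477, adjusted p = 0.444 with an estimated correlation). Pharynx markers had 5 of 16 higher (8 alone, median 1.89, adjusted p = 0.00897, adjusted p = 0.434 with an estimated correlation).

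**Figure D3:**
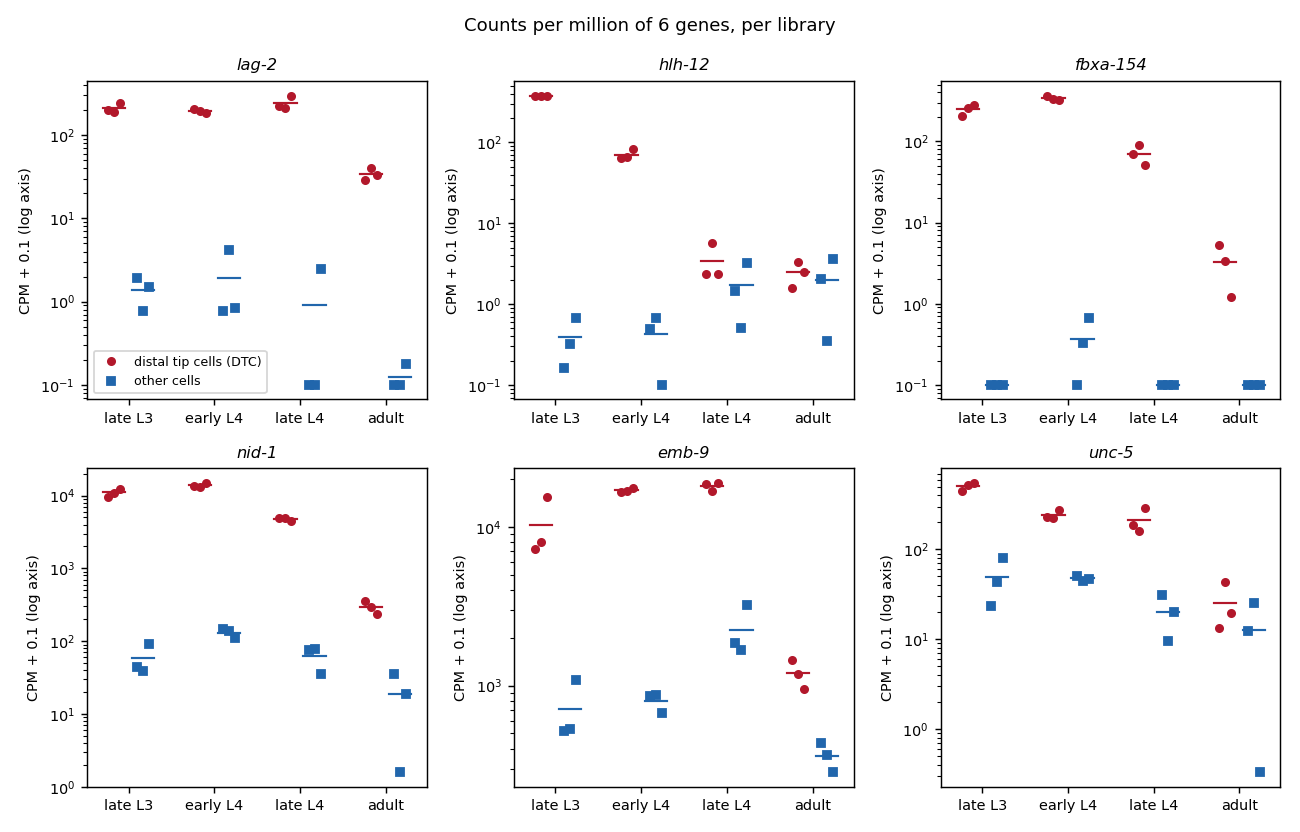
CPM + 0.1 (log axis) of lag-2, hlh-12, fbxa-154, nid-1, emb-9 and unc-5 by stage; points are single libraries, lines are means of 3, circles are DTCs and squares other cells. In DTCs hlh-12 averaged 375 CPM at late L3, 70.6 at early L4, 3.36 at late L4 and 2.38 in adults, while lag-2 averaged 209, 194, 245 and 34.

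Any difference among the 4 stages in DTCs was called for 6285 of 16887 genes. From late L3 to early L4, the genes that rose most included sperm genes, while lag-2 (0.03 ± 0.80) was not called. Nor was hlh-12 (-2.25 ± 0.77, adjusted p = 0.135), its libraries at 372 to 381 CPM, then 63.3 to 83.1. Counts rose from 0 to 3128 for acs-10, 3020 for clec-79, 995 for msp-3, 961 for spch-2 and 554 for msp-36. Rises were at least 1070-, 1030-, 341-, 329- and 190-fold. Also higher were nsph-2 (at least 306-fold), snf-9 (at least 225-fold), ssp-10 (at least 204-fold), msp-31 (8.91 ± 1.79) and msp-50 (5.33 ± 0.94). So were the cuticle or eggshell genes bli-6 (6.73 ± 1.46), col-140 (5.05 ± 0.82) and perm-4 (4.94 ± 0.96). Adhesion genes unc-95 (3.66 ± 0.66), pat-2 (2.99 ± 0.64) and unc-112 (1.46 ± 0.34), din-1 (1.66 ± 0.37), atf-4 (1.37 ± 0.31) and the guidance receptor sax-3 (1.14 ± 0.28) rose. Genes that fell were plag-15 (-2.78 ± 0.54), skpo-1 (-2.72 ± 0.54), dnj-27 (-2.72 ± 0.52), scpl-3 (-2.50 ± 0.57), btb-14 (-2.39 ± 0.58), inx-5 (-2.12 ± 0.43), lim-9 (-1.72 ± 0.29) and prmt-9 (-1.63 ± 0.40). This step called 338 genes (302 and 36), but 19 and 60 without late L3 replicate 1 or 2, and 35 and 45 without early L4 replicate 1 or 2. Of the 27 genes called and named by the rule, only col-140 was kept in every such fit, and 17 under every other setting. Sperm markers had 25 of 56 higher (47 alone, median 6.59, adjusted p = 4.57e-34, adjusted p = 0.468 with an estimated correlation). At early L4 their DTC share was 0.188% against 0.867% in other cells, so their source is open. Genes of the basement membrane had 1 of 25 higher (6 and 1 alone, median 0.57, adjusted p = 0.0171, adjusted p = 0.468 with an estimated correlation), with 4 higher under RLE.

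From early to late L4, genes that rose in the DTC fraction included yolk and cuticle genes, and genes that fell included some of molting, secretion and tubulin. Counts rose from 0 to 3059 for vit-5 (at least 1260-fold), from 0 to 1043 for nas-20 (at least 431-fold) and from 2 to 4461 for col-143, a ratio of 2770 (765 to 22800). Others that rose were vit-6 (12.08 ± 1.92), ssp-37 (at least 155-fold higher), spex-3 (at least 133-fold higher), the adult collagen gene col-19 (10.06 ± 1.06), vit-2 (9.78 ± 1.27) and col-140 (8.99 ± 0.88), and ule-1 went from 0 to 288 counts. So did lin-14 (3.55 ± 0.90), metalloprotease inhibitor timp-1 (2.62 ± 0.57), zmp-4 (2.48 ± 0.38), zyx-1 (2.28 ± 0.29), the autophagy regulator hlh-30 (2.25 ± 0.32) and the innexins inx-8 (1.36 ± 0.35) and inx-9 (1.35 ± 0.29). The migration factor hlh-12 (-4.38 ± 0.85) fell from 70.6 ± 10.8 to 3.36 ± 1.91 CPM (SD, n = 3), and lag-2 (0.40 ± 0.80, adjusted p = 0.851) was not called. Some apical matrix and molting genes fell, with dpy-7 going from 587 counts to 2, a ratio of 237 (65.2 to 1960). Others of this kind were lpr-3 (-6.91 ± 1.69), wrt-10 (-6.02 ± 1.38), noah-1 (-5.42 ± 0.80), lpr-1 (-5.25 ± 1.34), dpy-3 (-4.83 ± 1.03) and sym-1 (-4.11 ± 0.75). Adhesion and matrix genes ncam-1 (-4.60 ± 0.73), him-4 (-2.24 ± 0.40), lam-2 (-1.68 ± 0.46) and ina-1 (-1.13 ± 0.32) fell, with the timing genes lin-42 (-3.17 ± 0.76) and din-1 (-1.97 ± 0.37). Tubulin genes tba-1 (-1.56 ± 0.20), tba-2 (-1.09 ± 0.18) and tbb-2 (-1.02 ± 0.19) and the secretory genes pdi-6 (-2.03 ± 0.35), hsp-3 (-1.47 ± 0.28), copb-2 (-1.44 ± 0.21) and crt-1 (-1.29 ± 0.26) fell.

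The step from early to late L4 called 940 DTC genes (641 and 299), with 509 and 481 without early L4 replicate 1 or 3 and 570 and 602 without late L4 replicate 1 or 2. The calls of ina-1 and lam-2 were lost in such fits and under RLE, and those of lin-14, lin-42, timp-1, inx-8, lpr-1, lpr-3 and wrt-10 in such fits. ER to Golgi genes had 10 of 32 lower and 1 higher (11 and 1 alone, median -0.78, adjusted p = 8.41e-09, adjusted p = 0.0513 with an estimated correlation). ER folding genes had 10 of 27 lower (12 and 1 alone, median -0.86, adjusted p = 4.37e-08, adjusted p = 0.108 with an estimated correlation). Proteasome genes had 7 of 31 lower (24 alone, median -0.64, adjusted p = 2.91e-11, adjusted p = 0.108 with an estimated correlation), with 3 lower under RLE. Microtubule genes had 6 of 33 lower and 1 higher (8 and 1 alone, median -0.57, adjusted p = 1.69e-05, adjusted p = 0.0834 with an estimated correlation). Intestine markers had 9 of 21 higher (11 alone, median 1.75, adjusted p = 2.91e-11, adjusted p = 0.114 with an estimated correlation). Col collagens had 36 of 137 higher and 2 lower (46 and 4 alone, median 1.59, adjusted p = 1.64e-12, adjusted p = 0.25 with an estimated correlation).

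From late L4 to adult, when migration has ended, genes that fell in the DTC fraction included some of matrix, guidance and adhesion, and genes that rose some of yolk and muscle. Matrix genes that fell were nid-1 (-3.55 ± 0.60), mig-6 (-3.54 ± 0.36), emb-9 (-3.47 ± 0.38) and let-2 (-3.39 ± 0.43). Receptor and adhesion genes that fell were dgn-1 (-4.02 ± 0.30), sdn-1 (-2.88 ± 0.26), unc-97 (-2.81 ± 0.36), unc-5 (-2.70 ± 0.80), vab-1 (-2.49 ± 0.30) and unc-40 (-2.37 ± 0.37), with ina-1 (-2.33 ± 0.33), deb-1 (-1.93 ± 0.28) and pat-3 (-1.86 ± 0.34). So did fbxa-154 (-3.97 ± 0.66), lin-42 (-3.64 ± 0.82), flp-10 (-2.13 ± 0.40), apx-1 (-2.07 ± 0.53), inx-9 (-1.96 ± 0.29), pha-4 (-1.59 ± 0.31) and alg-1 (-1.56 ± 0.30). The niche ligand lag-2 (-2.43 ± 0.85, adjusted p = 0.0652), gon-1 (-0.68 ± 1.23, adjusted p = 0.753) and hlh-12 (-0.07 ± 0.78, adjusted p = 0.977) were not called. Among collagens and genes near them, idpc-3 went from 1222 counts to 0 (at least 389-fold lower), col-49 from 969 to 1, a ratio of 925 (166 to 36600), and col-79 from 843 to 2, a ratio of 402 (111 to 3330). The yolk genes vit-4 (7.96 ± 1.19), vit-3 (7.84 ± 1.46), vit-5 (6.65 ± 1.04), vit-6 (6.65 ± 1.46) and vit-2 (6.02 ± 1.06) rose. So did ule-5 (7.36 ± 1.34), ttr-42 (7.22 ± 0.82), ule-1 (6.89 ± 1.24), clec-222 (6.51 ± 0.85), the pharynx myosins myo-1 (4.40 ± 0.63) and myo-2 (4.21 ± 0.74), and metallothionein mtl-1 (3.98 ± 0.70). Also higher were hsp-12.3 (3.81 ± 0.52), asp-2 (3.41 ± 0.65), tni-3 (2.63 ± 0.56), aldo-2 (2.16 ± 0.32), nmy-1 (1.27 ± 0.32) and ATP synthase atp-1 (1.07 ± 0.23). The step called 2162 genes (1128 and 1034), with 1280 without late L4 replicate 3 and 1354 without adult replicate 3. The calls of unc-5 and nmy-1 were lost when some library was left out, and those of apx-1 and atp-1 without adult replicate 3.

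Lists that fell from late L4 to adult with either correlation began with niche genes, which had 6 of 15 lower (8 alone, median -1.96, adjusted p = 0.000196). Basement membrane genes had 12 of 25 lower and 3 higher (12 and 4 alone, median -1, adjusted p = 1.64e-08) and integrin genes 11 of 26 lower and 3 higher (14 and 5 alone, median -1, adjusted p = 0.000238). Guidance genes had 12 of 34 lower and 1 higher (12 and 2 alone, median -0.49, adjusted p = 0.000587) and timing genes 6 of 24 lower and 2 higher (8 and 2 alone, median -1.17, adjusted p = 0.00945). Oxidative phosphorylation genes had 23 of 45 higher and 2 lower (32 and 3 alone, median 0.79, adjusted p = 7.28e-08, adjusted p = 0.234 with an estimated correlation). Intestine markers had 11 of 21 higher (16 alone, median 2.86, adjusted p = 7.03e-10, adjusted p = 0.118 with an estimated correlation). Muscle markers had 10 of 23 higher (16 alone, median 1.73, adjusted p = 3.18e-07, adjusted p = 0.275 with an estimated correlation). Neuron markers had 10 of 58 higher and 1 lower (18 and 3 alone, median 1.69, adjusted p = 3.49e-05, adjusted p = 0.478 with an estimated correlation). In the same libraries intestine genes rose from 0.239% to 7.59% of counts and muscle genes from 1.05% to 2.95%. Germline genes fell from 0.146% to 0.0741% and hypodermis genes from 0.158% to 0.0146%.

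**Figure D4:**
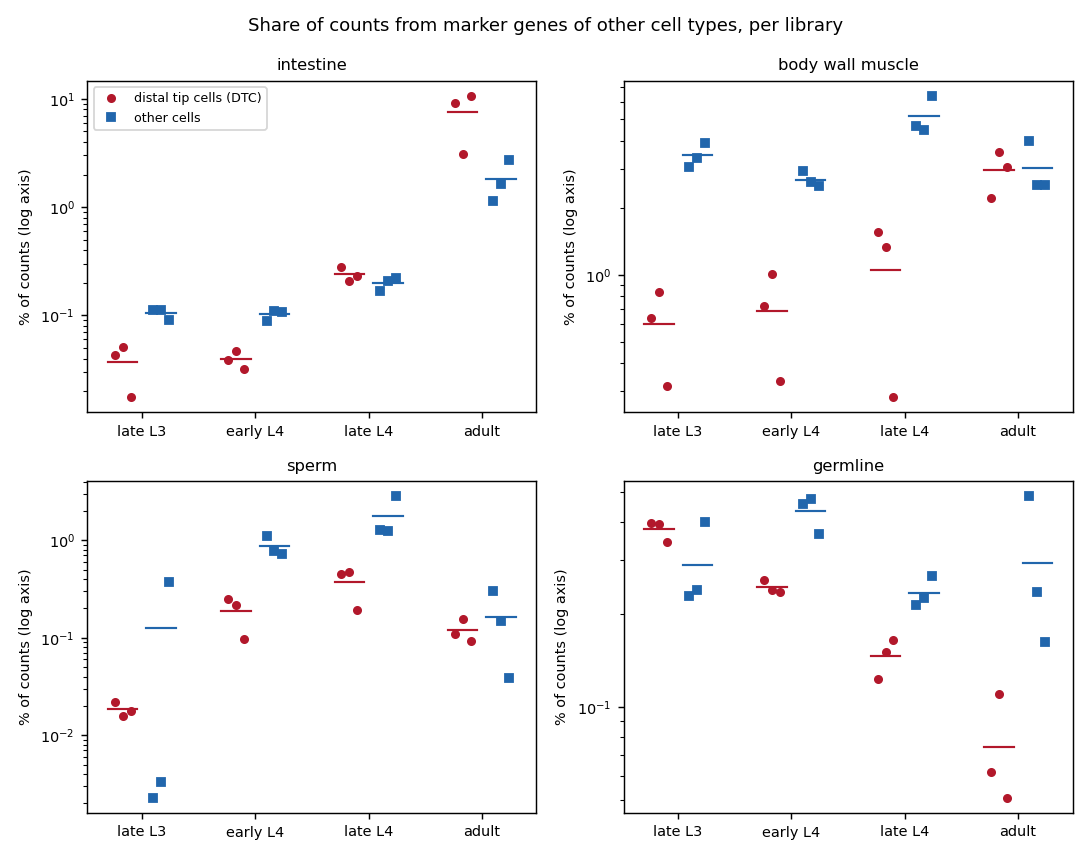
Share of a library's counts (%, log axis) from marker genes of intestine, body wall muscle, sperm and germline by stage; points are single libraries, lines are means of 3, circles are DTCs and squares other cells. Intestine genes averaged 7.59% of counts in adult DTCs against 1.84% in adult other cells, and germline genes 0.0741% against 0.294%.

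In other cells, which give the background of stage change, the genes that rose from late L3 to early L4 included col-63 (10.19 ± 1.41), col-138 (6.85 ± 1.43), rol-1 (6.41 ± 1.16), col-119 (5.75 ± 1.07), col-181 (4.71 ± 0.78) and col-140 (4.06 ± 0.71). The eggshell genes perm-4 (5.37 ± 0.92) and cpg-1 (2.24 ± 0.40), and ttr-14 (6.11 ± 1.29), rose, and try-14 had 304 counts against 1, a ratio of 296 (52.7 to 11700). Genes that fell were lron-2 (-3.84 ± 0.72), the linker histone genes hil-3 (-3.73 ± 0.61) and his-24 (-3.62 ± 0.74), scpl-3 (-2.72 ± 0.57), pha-4 (-2.71 ± 0.32) and rrn-2.1 (-1.90 ± 0.29). Also lower were pck-1 (-1.75 ± 0.32), ctn-1 (-1.73 ± 0.34), alg-1 (-1.55 ± 0.29) and spectrin spc-1 (-1.30 ± 0.28), and RLE ended the calls of scpl-3, ctn-1, spc-1 and alg-1. This step called 61 genes (34 and 27, or 41 and 9 under RLE), but 1421 (1066 and 355) without late L3 replicate 3. It called 15 and 14 without late L3 replicate 1 or 2, and 24, 32 and 38 without early L4 replicate 1, 2 or 3. Without late L3 replicate 3, sperm markers had 50 higher (median 8.64), against 0 called with it (median 2.65, adjusted p = 5.38e-36, adjusted p = 0.0891 with an estimated correlation). Of the 20 genes called and named by the rule, only col-63, try-14, pha-4 and rrn-2.1 kept their calls whichever library was left out. All 20, these 4 included, lost their calls in a fit of only the groups compared, which called 2 genes.

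Lists lower at early L4 than at late L3 in other cells, with either correlation, held few called genes. Guidance genes had 0 of 34 lower (3 and 1 alone, median -0.86, adjusted p = 6.97e-05). Integrin genes had 0 of 26 lower (2 alone, median -0.58, adjusted p = 0.00017) and actin genes 1 of 48 lower (6 alone, median -0.48, adjusted p = 0.000162). Heat shock genes had 0 of 23 lower (5 alone, median -0.68, adjusted p = 0.000254) and timing genes 1 of 24 lower (3 alone, median -1.08, adjusted p = 0.000254). Under RLE no actin or timing gene was called, and without late L3 replicate 3 the 5 lists had 2, 1, 4, 4 and 3 lower. Col collagens had 7 of 137 higher (19 and 5 alone, median -0.86, adjusted p = 0.854), the median and test differing in sign, and hypodermis markers 0 of 32 higher (1 alone, median 0.12, adjusted p = 0.433), and neither list passed. Without late L3 replicate 3 they had 18 higher and 4 lower, and 2 higher. The median of all genes in this step was -0.16, and 0.00 under RLE.

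From early to late L4 genes that rose in other cells included some of yolk, cuticle and basement membrane. Counts rose from 2 to 2700 for vit-5, a ratio of 1960 (543 to 16200), from 0 to 606 for clec-222 (at least 294-fold) and from 0 to 218 for ttr-42 (at least 106-fold). Genes that rose were cht-3 (10.47 ± 1.77), col-19 (9.55 ± 1.03), col-143 (9.39 ± 1.28), ule-5 (9.11 ± 1.45), ule-3 (8.96 ± 1.55), col-140 (7.54 ± 0.83) and vit-2 (7.53 ± 1.15). So did the eggshell genes perm-4 (7.05 ± 0.97) and perm-2 (6.33 ± 1.1), and vit-6 (6.94 ± 1.49) and timp-1 (4.06 ± 0.60). Basement membrane genes let-2 (2.05 ± 0.41), mig-6 (2.05 ± 0.34), emb-9 (1.88 ± 0.36) and the SPARC gene ost-1 (1.64 ± 0.31) rose, with nmy-1 (1.38 ± 0.32). Genes lpr-3 (-6.09 ± 1.59), wrt-10 (-5.15 ± 1.28), dao-2 (-5.13 ± 1.33), noah-1 (-5.09 ± 0.78), sym-1 (-4.54 ± 0.76), dpy-8 (-4.10 ± 1.03) and dpy-11 (-1.80 ± 0.41) fell. The step called 353 genes (312 and 41), with 201, 229 and 170 without early L4 replicate 1, 2 or 3. The calls of emb-9 and let-2 were lost without early L4 replicate 3, and those of vit-6, nmy-1, lpr-3, wrt-10, dao-2, dpy-8 and dpy-11 without some library, with lpr-3 and dao-2 also lost under RLE. Col collagens had 33 of 137 higher and 1 lower (49 and 5 alone, median 1.75, adjusted p = 5.48e-22, adjusted p = 0.106 with an estimated correlation). Genes of the basement membrane had 6 of 25 higher (9 and 1 alone, median 0.67, adjusted p = 0.000134, adjusted p = 0.0768 with an estimated correlation). Hypodermis markers had 5 of 32 lower (9 alone, median -2.65, adjusted p = 4.75e-12, adjusted p = 0.106 with an estimated correlation).

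From late L4 to adult genes that rose in other cells included yolk genes, and genes that fell some collagens. Yolk genes vit-3 (7.79 ± 1.47), vit-4 (6.90 ± 1.13), vit-1 (6.81 ± 1.26), vit-5 (5.13 ± 0.97), vit-6 (5.10 ± 1.36) and vit-2 (4.67 ± 1) rose. Also higher were col-101 (4.19 ± 0.78), clc-24 (4.04 ± 1.03), mtl-1 (4.04 ± 0.71) and the replication genes mcm-3 (1.51 ± 0.29) and mcm-4 (1.11 ± 0.29). Counts fell from 6093 to 0 for idpc-3 (at least 2160-fold lower) and from 9833 to 3 for abu-14, a ratio of 3480 (1190 to 16900). They fell from 185 to 0 for gpn-1 (at least 65.5-fold lower) and from 97 to 0 for lin-14 (at least 34.3-fold lower). Genes grl-5 (at least 757-fold lower), bus-8B (at least 360-fold lower), col-110 (at least 262-fold lower), grl-15 (at least 156-fold lower) and col-49 (-10.26 ± 1.29) fell, as did hhat-1 (at least 228-fold lower), which lies within the span of unc-52 on the opposite strand. Matrix and adhesion genes epi-1 (-3.42 ± 0.38), mig-6 (-2.74 ± 0.35), pat-2 (-2.65 ± 0.63), let-2 (-2.57 ± 0.42), emb-9 (-2.39 ± 0.37) and ost-1 (-2.17 ± 0.31) fell, with nmy-1 (-1.18 ± 0.32). The step called 1133 genes (347 and 786, or 144 and 1044 under RLE), with 470 and 520 without late L4 replicate 1 or 2 and 437 and 507 without adult replicate 2 or 3. The calls of vit-2, vit-6, clc-24, mcm-3, grl-5, grl-15, bus-8B, hhat-1, pat-2 and nmy-1 were lost without some library, as was mcm-4, which RLE also ended. Of the 30 genes called and named by the rule, 13 kept their calls under every other setting, and voom ended those of idpc-3, abu-14, col-110 and col-49. The basement membrane list had 10 of 25 lower (13 alone, median -1.65, adjusted p = 5.01e-13), with either correlation. Col collagens had 61 of 137 lower and 2 higher (71 and 6 alone, median -4.06, adjusted p = 3.82e-18, adjusted p = 0.438 with an estimated correlation). Hypodermis markers had 12 of 32 lower (16 alone, median -3.50, adjusted p = 2.77e-05, adjusted p = 0.438 with an estimated correlation).

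Whether DTCs changed differently was tested as the DTC step minus the step in other cells. Over all steps 2354 genes differed, fewer with the block and 1508 without adult DTC replicate 3. From late L3 to early L4 the genes above included heh-1, pat-2, sorb-1, pkg-2, pha-4 and sax-3, and try-14 and skpo-1 lay below. The 84 genes (74 and 10) became 13 and 33 without DTC late L3 replicate 1 or 2, and 18, 25 and 26 without DTC early L4 replicate 1, 2 or 3. For other cells these counts were 22 and 23, and 20, 24 and 17. They were 223 and 210 without late L3 replicate 3 of DTCs or of other cells, and of the 15 genes called and named by the rule only sorb-1, pkg-2 and pha-4 kept their calls in every such fit. RLE also ended the call of sax-3. With the replicate number as a block 18 genes were called, and of the 15 only heh-1, try-14, pkg-2 and pha-4 kept their calls. Only pkg-2 and pha-4 kept theirs under every other setting. Guidance genes had 1 of 34 higher (6 alone, median 1.44, adjusted p = 9e-08), 0 under RLE, and integrin genes 3 of 26 higher (9 alone, median 0.98, adjusted p = 1.11e-05). Actin genes had 2 of 48 higher (3 alone, median 0.53, adjusted p = 7.95e-05) and basement membrane genes 0 of 25 higher (3 alone, median 1.11, adjusted p = 0.000218). Muscle markers had 0 of 23 higher (0 alone, median 1.49, adjusted p = 2.5e-07, adjusted p = 0.279 with an estimated correlation), pharynx markers 1 of 16 higher (7 alone, median 2.58, adjusted p = 2.5e-07, adjusted p = 0.157 with an estimated correlation) and neuron markers 0 of 58 higher (0 alone, median 1.35, adjusted p = 2.2e-05, adjusted p = 0.409 with an estimated correlation).

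From early to late L4 hlh-12 fell in DTCs relative to other cells. So did skpo-1, amx-2, lron-2, unc-89, clik-3 and spp-10. Laminin genes lam-2 and epi-1, papilin mig-6 and tubulin genes tba-1 and tba-2 lay below. Genes above were mps-2, acs-2, adh-1, alh-1 and fkh-7. As hlh-12 lies within the span of spp-10 (IV 8477180 to 8480656, opposite strand) and the strand setting is not known, these changes are not certain to be separate. The step called 64 genes (28 and 36). Without DTC early L4 replicate 1 or 3 it called 35 and 28, and without DTC late L4 replicate 3 it called 35. Without other cells of early L4 it called 27, 30 and 38, and without late L4 replicate 1 of them 42. The calls of lam-2, epi-1, mig-6, tba-1, tba-2, acs-2 and adh-1 were lost in some such fit, that of acs-2 also under RLE. The replicate number as a block ended the calls of hlh-12, unc-89, fkh-7, lam-2, epi-1, mig-6, tba-1 and tba-2, and called 27 genes. Basement membrane genes had 3 of 25 lower (8 alone, median -1.07, adjusted p = 4.11e-07) and actin genes 0 of 48 lower (2 alone, median -0.28, adjusted p = 0.000143).

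From late L4 to adult genes that fell in DTCs relative to other cells included the Frizzled gene mig-1, dgn-1, vab-1, smp-1 and unc-40, with sdn-1, ina-1, unc-97 and inx-9. Others below were fbxb-88, sex-1, the Notch-cleaving protease gene sup-17 and the germ granule gene pgl-1. Genes above were abu-14, lron-2, gplb-1, perlecan unc-52, tni-3, myo-1 and nmy-1. The step called 1206 genes (564 and 642, or 690 and 359 under RLE, which moved the median of all genes from 0.17 to 0.46). Without DTC late L4 replicate 3 it called 428, and without DTC adult replicate 1 or 3 it called 794 and 582. Without late L4 replicate 1 or 2 of other cells it called 734 and 764, and fbxb-88 and pgl-1 were lost in some such fit. Voom ended the calls of abu-14 and lron-2, and 21 of the 31 genes called and named by the rule kept their calls under every other setting. Niche genes had 4 of 15 lower (7 alone, median -1.55, adjusted p = 0.000604), with either correlation. Guidance genes had 8 of 34 lower and 2 higher (10 and 6 alone, median -0.44, adjusted p = 0.0214, adjusted p = 0.439 with an estimated correlation), with a mean of 0.53 and a median of -0.16 under RLE. Integrin genes had 5 of 26 lower and 1 higher (7 and 4 alone, median -0.61, adjusted p = 0.0866), or 3 lower and 2 higher under RLE, and did not pass. Muscle markers had 7 of 23 higher (17 alone, median 2.49, adjusted p = 1.82e-10, adjusted p = 0.439 with an estimated correlation), with 11 higher under RLE. Pharynx markers had 4 of 16 higher and 1 lower (9 and 1 alone, median 3.16, adjusted p = 0.000233, adjusted p = 0.439 with an estimated correlation).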

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

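Every test of an explanation in this part, and every split of the libraries, was chosen only after the result it addresses was seen. Results stand here because a test of the difference itself showed that DTCs and other cells changed differently between stages.

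Any such difference was called for 2354 genes, and for 84, 64 and 1206 in the 3 steps by stage, each lower with the block. When the fraction labels were split at random within each stage, 1 of 25 splits, the real one, gave as many genes for each of these 4 counts. The highest of the others were 1, 2, 1 and 3, but such splits mix the 2 fractions, which widens the spread, so they do not say whether chance could give these counts. For the mean over stages the real split gave 5163 genes and the others 0, with the same limit.

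From late L3 to early L4, brackets giving the difference of log2 fold changes ± standard error, DTCs lay above in heh-1 (4.31 ± 0.74), pat-2 (4.01 ± 0.87), unc-95 (3.95 ± 0.86), bca-1 (3.89 ± 0.74), sorb-1 (3.48 ± 0.55) and pkg-2 (3.44 ± 0.47). The same held for clec-1 (3.41 ± 0.67), sec-3 (3.38 ± 0.72), pha-4 (2.90 ± 0.44), dnj-7 (2.17 ± 0.45), twf-2 (1.87 ± 0.40), unc-78 (1.86 ± 0.37) and sax-3 (1.75 ± 0.39). They lay below in try-14 (fitted -7.09 ± 1.36, a ratio of 243, 42.2 to 9760) and skpo-1 (-4.15 ± 0.78). The largest adjusted p of these was 0.0489, for sax-3. Only pkg-2 and pha-4 kept their calls both whichever library was left out and with the replicate number as a block.

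From early to late L4 DTCs lay above in mps-2 (4.85 ± 0.60), acs-2 (4.02 ± 0.86), adh-1 (3.29 ± 0.60), unk-1 (3.14 ± 0.65), alh-1 (2.99 ± 0.37), sto-4 (2.97 ± 0.58), nhr-101 (2.95 ± 0.60) and fkh-7 (2.37 ± 0.40). They lay below in hlh-12 (-7.09 ± 1.22), skpo-1 (-6.59 ± 0.79), amx-2 (-5.78 ± 0.89), lron-2 (-5.52 ± 0.97), unc-89 (-3.34 ± 0.52), clik-3 (-3.30 ± 0.57) and spp-10 (-3.20 ± 0.40). Smaller differences below 0 were those of lam-2 (-3.16 ± 0.66), mig-6 (-2.57 ± 0.47), epi-1 (-2.53 ± 0.50), pdi-6 (-2.27 ± 0.48), tba-1 (-1.45 ± 0.27) and tba-2 (-1.32 ± 0.25). The largest adjusted p was 0.0416, for acs-2. Calls kept whichever library was left out were those of mps-2, alh-1, fkh-7, hlh-12, skpo-1, amx-2, lron-2, unc-89, clik-3 and spp-10.

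From late L4 to adult DTCs lay above in abu-14 (fitted 8.15 ± 1.60, a ratio of 288, 97.4 to 1400), lron-2 (fitted 8.05 ± 1.59, at least 21.9-fold), col-135 (7 ± 1.72), pqn-74 (6.21 ± 1.58), ule-5 (6.17 ± 1.55), ule-3 (5.98 ± 1.67) and gplb-1 (5.98 ± 0.85). The same held for bgal-1 (5.82 ± 0.75), unc-52 (4.79 ± 0.90), tni-3 (3.82 ± 0.77), cup-4 (3.81 ± 0.90), myo-1 (3.54 ± 0.80) and nmy-1 (2.44 ± 0.46). They lay below in fbxb-88 (-5.51 ± 1.38), mig-1 (-4.67 ± 0.70), sex-1 (-4.60 ± 0.92), coh-4 (-4.14 ± 0.90), lact-4 (-3.90 ± 0.79), dhhc-9 (-3.89 ± 0.52) and sup-17 (-3.88 ± 0.54). Also below were cca-1 (-3.87 ± 0.88), dgn-1 (-3.57 ± 0.39), vab-1 (-3.57 ± 0.41), smp-1 (-3.52 ± 0.49), unc-40 (-2.97 ± 0.51) and sdn-1 (-2.72 ± 0.35). The last were ina-1 (-2.58 ± 0.45), unc-97 (-2.56 ± 0.48), inx-9 (-2.41 ± 0.41), pgl-1 (-2.29 ± 0.52) and mcm-3 (-1.68 ± 0.40). The largest adjusted p was 0.0386, for ule-3. Leaving out some library ended the calls of col-135, pqn-74, ule-5, ule-3, fbxb-88, cup-4, mcm-3 and pgl-1, and of no other gene in this paragraph.

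In a fit of only the 12 DTC libraries, 1 of 60 random splits by stage, the real one, gave as many as its 6423 genes for any difference among stages. The highest other split gave 949, but such splits mix stages. For single comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05, and in each the real split was the only 1 of its size. Fits of only the 6 libraries compared gave 1061, 4129, 2362 and 395 genes for DTCs against other cells from late L3 to adult. They gave 722, 1431 and 2333 for the DTC steps and 2, 929 and 592 for the steps in other cells, and the highest other split gave 0 in every case, at late L3 also where it parted as many numbered pairs.

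Intestine genes had a higher share of counts in adult DTC libraries than in adult other cells, yolk genes alone taking 2.94% to 10.2% against 0.999% to 2.47%. DTC samples that were merely a general mixture of other cells are argued against, since the germline list had a median log2 fold change of -1.49 in adult DTCs against other cells (quartiles -2.12 and -1.29), where such a mixture would leave it near 0. Intestinal cells or their RNA in the Venus-positive fraction remain open: the 15 genes other than yolk genes of the list (21 genes, 4 also in another list, 20 with at least 1 CPM in late L4 DTCs) had a median log2 fold change of 1.36 with 14 higher, against 1.66 for the 6 yolk genes, but they took 0.16% to 0.368% of counts against 0.138% to 0.267%, and the list had an adjusted p = 0.444 with an estimated correlation. Only act-5, ifc-2 and ftn-1 were called, at 501, 212 and 45.4 CPM against 271, 46.6 and 6.46. Fold changes ran from -0.04 (lys-8) to 3.5 (elt-2), with elt-7 at 2.76. Intestinal cells thus cannot be told apart from expression of these genes by adult DTCs, which was not tested.

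Other cells late L3 replicate 3 stood apart in sperm and hypodermis share. A swap with an early L4 library of other cells is argued against. The lowest share of the 57 sperm genes (0 in another list) there was 0.723%, none out of place. A swap with a sample from outside needs no partner. Early L4 RNA mixed into the library is argued against as well. The sperm share would allow 42.8% of such RNA and thus a fall of at most -0.81, while 76 genes at least 8-fold lower at early L4 than in 1 of the 2 replicates had a median of -2.69 (quartiles -3.81 and -1.50) against the other, and -2.97 for 81 genes with the 2 exchanged. Animals later in development cannot be told apart from other causes of this, as the 302 genes called higher in DTCs at early L4 had a median difference of 1.33 in this library, but the 191 outside the sperm list that did not vary with it (correlation under 0.8) had 0.04 (quartiles -0.61 and 1.16), and the 36 called lower had -0.1.

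The fall of DTC genes from late L4 to adult covered 107 genes with at least 10 CPM, at least 8-fold above other cells at late L4 and at least 64-fold above adult other cells, with a median of -3.09 (quartiles -3.93 and -2.58), 53 of them called lower. As they were chosen for being high at late L4, after a median rise of 0.97 from early L4, part of the fall may follow from the choice. As the whole cause, not a part, dilution by the general mixture of other cells is argued against by the germline list. Its adult median against other cells was -1.49, all 29 genes (1 also in another list) below the -0.18 this allows. A few abundant genes as the whole cause are argued against too. The 10 most abundant of an adult DTC library held at most 33.68% of counts, a loss of at most -0.59. A lower share of DTC RNA beside more RNA of other somatic cells cannot be told apart from a fall within DTCs: 10.3% of the genes fell by an amount over 2 standard errors from the median, and no value here bounds that share, so an end of the migration programme, the biological explanation, stays open and untested.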

How the results depend on the processing

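Settings without rRNA genes, with the larval mean and without other cells late L3 replicate 3 were chosen after seeing results. Counts below are genes called, in order of stage, and where a setting moved a count the cause was not tested.

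DESeq2 called 3999, 2960, 3330 and 3980 genes for DTCs against other cells by stage, where edgeR called 2256, 1866, 1992 and 2248. It called 1711, 2052 and 3854 for the DTC steps (338, 940 and 2162 in edgeR) and 556, 1063 and 3026 for the steps in other cells (61, 353 and 1133). For the difference between fractions it called 4564 in any step (2354) and 630, 336 and 2603 per step (84, 64 and 1206). Voom called 5239, 6251 and 4054 at the larval stages, 11544 for any difference among DTC stages (6285) and 4509, 3814 and 4173 for the DTC steps. It called 4775 and 1765 for the first 2 steps in other cells, and 6296 in any step and 2635 and 433 in the first 2 for the difference between fractions. In simulated late L3 data DESeq2 and voom made more false calls than edgeR.

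Without a filter the step from late L3 to early L4 called 885 genes in DTCs, 159 in other cells and 149 for their difference. Fits of only the groups compared called 1061 at late L3, 4129 at early L4 and 395 in adults, and 722 and 1431 for the first 2 DTC steps. They called 2, 929 and 592 for the steps in other cells, and 175 and 484 for the last 2 differences between fractions. Every count under RLE scaling and without rRNA genes stayed within 1.5 times, as did the larval mean with 6048 against 5163.

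The replicate number as a block called 213 and 38 genes for the step from late L3 to early L4 in DTCs and other cells, 1363 for the difference between fractions in any step and 18, 27 and 517 per step. For DTCs against other cells at late L3 the block called 1700 of the 16887 genes. Of the named genes and printed lists there, it changed only the calls of the coelomocyte list, vit-6 and nsph-3.1. At the other stages it called 1524, 1657 and 1612.

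With 1 library left out in turn, the mean over stages called 4303 to 5693 genes. Single stages called 1224 to 1885, 1105 to 1612, 1157 to 1721 and 1180 to 2387. Any difference among DTC stages called 4912 to 6176, with 19 to 268, 481 to 818 and 1280 to 2017 for the DTC steps. Steps in other cells called 14 to 1421, 170 to 335 and 437 to 1292, and differences between fractions 1508 to 2606 in any step and 13 to 223, 27 to 55 and 428 to 1241 per step.

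Of 476 list tests 239 passed at the preset correlation, 46 with an estimated correlation (all among the 239), 201 by fry in 1 direction and 240 with the block, 234 of them shared. Of 501 pairs of a named gene and a comparison that was called, 362 kept their call with every library left out and 363 under every other setting. None of the 501 turned direction in these fits. Changes of up to 8-fold between single groups are mostly missed at this replication, and the lowest library had 8391423 counts.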

Other observations

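No test of an explanation was chosen for this part, and the lists are those written before the data were examined.

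In the DTC fraction from early to late L4, intestine markers, tested above, went from 0.0393% to 0.239% of counts. Hypodermis markers had 6 of 32 lower (8 alone, median -1.78, adjusted p = 1.54e-08, adjusted p = 0.188 with an estimated correlation).

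At late L3, against other cells, pharynx markers had 8 of 16 lower and 1 higher (11 and 1 alone, median -3.05, adjusted p = 2.82e-05, adjusted p = 0.194 with an estimated correlation) and glia markers 3 of 9 lower (6 alone, median -3.05, adjusted p = 0.000108, adjusted p = 0.0881 with an estimated correlation), with 5 lower under RLE. Germline markers had 2 of 29 higher (2 alone, median 0.49, adjusted p = 0.0408, adjusted p = 0.558 with an estimated correlation) and oocyte markers 2 of 19 higher (1 alone, median 0.79, adjusted p = 0.00443, adjusted p = 0.445 with an estimated correlation), or 5 higher without other cells late L3 replicate 3 (median 1.22).

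In adult other cells replicate 1 rRNA took 11.19% of counts against 33.21% and 32.63% in replicates 2 and 3.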
